A study of Mus musculus with 23 samples.

How the data were processed

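Tumour barcode sequencing (Tuba-seq) was run by the authors on genomic DNA of tumour-bearing lungs of 23 labelled mice in a mixed BL6/129 strain, 4 months after tumour start. The groups KT, KT_Cas9 and KTL_Cas9 follow the genotypes in the labels, which give no replicate numbers, so mice were numbered in the order of their records. The deposited table gives for each mouse, vector identifier and 30-base barcode a read count, and per the file headers it also holds the vector name, an estimated cell number and a ratio of cells per read for the mouse. The deposited counts are whole numbers from 2 upwards with no normalisation. The deposited ratio equals 500000 divided by a read number given per mouse, taken here as the mean reads of a standard of 500000 cells, and the deposited cell number equals count times ratio. How that standard was made, and the read processing, are not given in the sources used here.

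The table held 1019578 lines, of which 913708 were distinct. Every line of KT replicate 2 stood 2 times (211740 lines), and the 105870 repeats were dropped. KT replicate 4 had no lines and was not analysed here. KTL_Cas9 replicate 1 had 76271 reads, 17 tumours and 0 inert tumours, and was left out, so 21 of 22 mice entered the comparisons. Barcodes without a vector name (48400 lines, 1.76% of reads) and 2 identifiers not named as vectors were left out. Near-identical barcodes were not merged, because none lay 1 mismatch from another with 20 times its reads. Of 843190 pairs of vector and barcode, 20283 (2.41%) occurred in more than 1 mouse, and they were kept.

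A tumour was a barcode of a named vector with at least 500 estimated cells. Size per vector and mouse was the log-normal mean (maximum likelihood) of its tumours, taken as log2 ratio to the inert tumours of the same mouse (the vectors Neo1/NT and Neo1/NT/Neo2). Number was the log2 ratio of a vector's tumours to inert tumours. A vector needed 5 tumours in a mouse, a mouse 20 inert tumours and a group 4 mice (3 when a mouse was left out). The mouse was the replicate. Reads are PCR products without molecular identifiers, so read numbers are not independent molecules, and precision was taken from the spread between mice.

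Groups were compared by two-sided exact permutation of mouse labels (1001 splits for KT_Cas9 and KT, 330 for KTL_Cas9 and KT, 19448 for KTL_Cas9 and KT_Cas9), and values within a genotype by two-sided exact sign-flip permutation. Permutation of labels takes the spread as equal in both groups. Its p can be too small where the smaller group varies more, as Sik multi-gene vectors did in KTL_Cas9 (SD 0.99) against KT_Cas9 mice (SD 0.44). Benjamini-Hochberg adjustment ran over the 24 targeting vectors, 15 class tests, 15 tests of size and number levels, or 14 contrasts per genotype, at a threshold of 0.05. In the alternatives, class differences and inert size were called on the unadjusted p at the same threshold. The measure, floor, tests, vector classes and most alternatives were fixed before the data were examined. Contrasts of Lkb1 guides, promoter positions and vector classes within mice (but not those of combination with single-gene vectors), level tests other than inert size, percentiles, shares of cells and the number comparison of KTL_Cas9 with KT_Cas9 were chosen after the file was read. By the rule fixed for naming, all 24 targeting vectors are named, since there are fewer than 30 of them. Of the 12 targeted genes, 10 matched the mouse gene table by name (Lkb1 as a synonym of Stk11), and Ampk1 and Ampk2 are kept as the file writes them. No genome coordinates were used.

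The tests were tested on simulated data, with 12 of 24 vectors changed by 1.5-, 2- or 4-fold in 20 runs. A changed vector had the same fold in every mouse of the changed groups, so spread of its effect between mice was absent. The real Sik multi-gene class had an SD of 0.44 in KT_Cas9 mice. The shares of changed vectors called may therefore be higher than for real vectors. When tumours past the floor were scaled, KT_Cas9 versus KT called 100% of changed vectors at every fold in the right direction, with median estimates of 0.59, 1.01 and 2.00 for increases, and called 0.833% of unchanged vectors. KTL_Cas9 versus KT called 7.5% of 1.5-fold increases and 10% of 1.5-fold decreases, 55% of 2-fold and 92.5% of 4-fold changes either way, and 0 of 240 unchanged vectors. When only KTL_Cas9 tumours were scaled, KTL_Cas9 versus KT_Cas9 called 52.5%, 85% and 100% of increases and 55%, 95% and 100% of decreases at 1.5, 2 and 4-fold, with 4.58% of unchanged vectors called higher and 4.17% lower. When every barcode was scaled before the floor, the KT_Cas9 versus KT size test called 7.5% of 4-fold increases, estimated at 0.62, and 0 of 40 4-fold decreases, while the number test called 97.5% of 1.5-fold increases and 100% of 1.5-fold decreases, with 6.25% of unchanged vectors called higher and 8.75% lower. In that comparison size therefore understates growth that shifts all clones alike, and such growth appears in number. In KTL_Cas9 versus KT a 4-fold decrease of every barcode gave -1.25 by size (0 of 40 called) and -0.40 by number (22.5% called). These simulations kept each vector's real number of barcodes. With no simulated change, number in KTL_Cas9 therefore lay at medians of 0.20 to 0.26 against KT and 0.22 to 0.26 against KT_Cas9. There 7.5% to 15.4% and 39.2% to 43.8% of vectors were called higher. The number test was therefore also run, after these values were seen, on tumours drawn at the vectors' shares in KT mice. KTL_Cas9 versus KT then called 92.5% of 1.5-fold increases, 70% of 1.5-fold decreases and 0 of 240 unchanged vectors. KT_Cas9 versus KT called 100% of 1.5-fold changes either way, and 0 of 240 unchanged vectors higher and 0.417% lower. With only KTL_Cas9 changed, KTL_Cas9 versus KT_Cas9 called 100% of 1.5-fold changes either way, and 2.08% of unchanged vectors higher and 3.75% lower.

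Work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 (quasi-likelihood tests on reads summed per vector and on tumour numbers, with inert reads or tumours as library size) and limma 3.58.1 (on the log2 ratios). Alternatives tried were the 95th and 90th percentile, median and arithmetic mean as size, floors 3 times lower and higher, merging at 1 mismatch, leaving out barcodes seen in more than 1 mouse, each inert vector and each mouse, at least 20 tumours of a vector, shares of reads in place of cells, edgeR and limma. Alternatives added after seeing the data were a floor 10 times higher, at least 10 reads per tumour, leaving out mice under 500000 reads, and leaving out the minor copies (under 5% of the reads) of barcodes seen in several mice.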

Results

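Barcoded lung tumours were counted and sized by sequencing genomic DNA of tumour-bearing mouse lungs 4 months after tumours were started with a pool of barcoded lentiviral Cre vectors. Each vector carried guide RNAs against named genes, and each tumour carried the vector identifier and a random barcode of the cell it grew from. The pool held 26 named vectors, of which 24 targeted genes and 2 were inert. The 24 comprised 10 vectors against Lkb1 (Stk11), a kinase that activates the AMPK-related kinases, 4 against Sik1 or Sik3 alone, 5 against 2 or more of the salt-inducible kinases Sik1, Sik2 and Sik3, and 5 against other AMPK-related kinases (Ampk1/Ampk2 in a dual and a triple vector, Nuak1/Nuak2, Mark2/Mark3/Mark4 and Snrk). All mice carried a Cre-dependent Tomato reporter. KT mice had no Cas9, so their guides could not act and they gave the background. KT_Cas9 mice carried Cre-dependent Cas9. KTL_Cas9 mice carried Cas9 and floxed Lkb1, so that Cre itself deletes Lkb1 in the tumours.

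The labels list 5 KT, 10 KT_Cas9 and 8 KTL_Cas9 mice, and 4, 10 and 7 of them entered the comparisons. Reads assigned to named vectors ran from 936090 to 1505173 per KT mouse, from 92713 to 4516887 per KT_Cas9 mouse and from 2181575 to 8547188 per KTL_Cas9 mouse. A tumour was a barcode with at least 500 estimated cells, which took 3.13 to 7.81 reads in KT, 3.76 to 12.01 in KT_Cas9 and 6.16 to 51.7 in KTL_Cas9 mice. The median number of tumours per mouse was 41380 in KT (20490 to 51273), 8226 in KT_Cas9 (2013 to 56334) and 1685 in KTL_Cas9 (879 to 4522). Inert tumours numbered 1496 to 3693, 125 to 4370 and 61 to 321 per mouse.

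The tumours with inert vectors give tumour size in each mouse group without a guide against a named gene. Genotype is not separated there from virus dose or other differences between the groups of mice. Inert tumours of KTL_Cas9 mice, in which Cre deletes Lkb1, were 29.6-fold larger than those of KT_Cas9 mice (log2 difference 4.89 ± 0.34 SE, n = 7 and 10). Their log-normal mean size per mouse had a geometric mean over mice of 38669 cells, against 1307 in KT_Cas9 and 2123 in KT mice. It was 18.2-fold larger than in KT mice (log2 difference 4.19 ± 0.37 SE, n = 7 and 4). Median inert sizes per mouse had geometric means of 4711 cells in KTL_Cas9, 804 in KT_Cas9 and 1063 in KT mice. Among tumours past the floor, the 95th percentile was 41.3-fold and the median 5.86-fold larger in KTL_Cas9 than in KT_Cas9 mice. KTL_Cas9 mice had 4.47-fold fewer tumours than KT_Cas9 mice and 17.3-fold fewer than KT mice, and the labels give no virus dose. In a two-sided exact permutation test of the mice the 29.6-fold difference had p = 5.14e-05, the smallest the design allows, and adjusted p = 0.000257 over 15 such tests. For KTL_Cas9 versus KT the exact permutation p was 0.00303, again the smallest possible (adjusted p = 0.00649). Inert tumours were smaller in KT_Cas9 than in KT mice (log2 difference -0.70 ± 0.22 SE, exact permutation p = 0.00799, adjusted p = 0.0120). This difference was 0.03 (exact permutation p = 0.971) on shares of reads without the cell-number standard and 0.23 (exact permutation p = 0.129) with the size floor 10 times higher. It also lost its call on arithmetic means (-0.38, exact permutation p = 0.456), with the floor 3 times lower (-0.68, p = 0.103) or higher (-0.21, p = 0.277) and at 10 or more reads (-0.77, p = 0.0589).

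**Figure D1:**
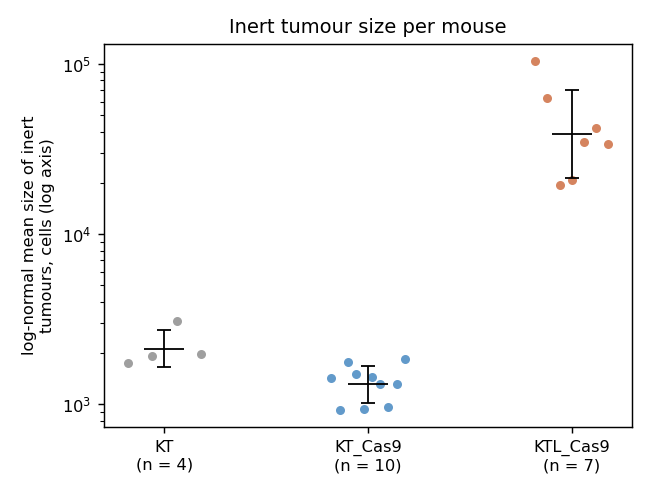
Log-normal mean size of tumours with inert vectors in estimated cells (log axis) per mouse, for 4 KT, 10 KT_Cas9 and 7 KTL_Cas9 mice. Each point is a mouse, and the bars give the group geometric mean ± SD on the log scale. Values ran from 1740 to 3088 cells in KT, from 926 to 1845 in KT_Cas9 and from 19495 to 103239 in KTL_Cas9 mice.

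The comparison of KT_Cas9 with KT mice asks which vectors changed tumour size where Lkb1 was intact. Vectors against 2 or more Sik genes and vectors against Lkb1 both enlarged tumours. Vectors against a single Sik gene or the other AMPK-related kinases did not pass against KT mice at the main setting with all mice in. In KT_Cas9 mice the Sik multi-gene vectors averaged a log2 size ratio to inert tumours of 0.95 ± 0.44 (SD, n = 10) with 10 of 10 mice above 0. Their value was 0.02 ± 0.06 (SD, n = 4) in KT mice, a 1.91-fold difference. The Lkb1 vectors averaged 0.93 ± 0.39 (SD, n = 10) with 10 of 10 mice above 0, against 0.04 ± 0.05 (SD, n = 4) in KT mice, a 1.85-fold difference. By exact permutation of mice, adjusted over 15 class tests, these differences had adjusted p = 0.0112 (Sik multi-gene) and 0.00749 (Lkb1), and all 9 Sik vectors together gave 0.58 ± 0.09 SE (adjusted p = 0.0112).

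Of the 24 targeting vectors, 14 gave larger and 0 gave smaller tumours in KT_Cas9 than in KT mice. All 5 Sik multi-gene vectors passed, and 5 when adjusted over the list alone. Their log2 differences were 0.88 ± 0.12 SE for Sik1 guide 1/Sik3 guide 1 (exact permutation adjusted p = 0.00799), 0.75 for Sik1 guide 1/Sik3 guide 2, 0.89 for Sik1 guide 2/Sik3 guide 1, 1.16 ± 0.24 SE for Sik1 guide 2/Sik3 guide 2 (exact permutation adjusted p = 0.0192) and 0.97 ± 0.15 SE for Sik1/Sik2/Sik3 (exact permutation adjusted p = 0.00599). Of the 10 Lkb1 vectors 9 passed, and 9 when adjusted over the list alone. The dual hU6-Lkb1 guide 1 vector had the largest difference of the 24, at 2.97-fold (log2 1.57 ± 0.21 SE, exact permutation adjusted p = 0.00599), followed by dual mU6-Lkb1 guide 1 at 1.34 ± 0.19 SE and triple hU6-Lkb1 guide 1 at 1.21 ± 0.22 SE. The other Lkb1 vectors that passed were triple bU6-Lkb1 guide 2 (0.87), dual mU6-Lkb1 guide 2 (0.85), triple mU6-Lkb1 guide 1 (0.81), dual hU6-Lkb1 guide 2 (0.77), triple bU6-Lkb1 guide 1 (0.71) and triple hU6-Lkb1 guide 2 (0.69). Triple mU6-Lkb1 guide 2 did not pass, at 0.03 ± 0.10 SE (exact permutation adjusted p = 0.864), and was -0.11 (adjusted p = 0.0461) with the size floor 3 times lower. Without KT replicate 1, and again without KT replicate 3, 9 of the 24 vectors passed. Sik1 guide 1/Sik3 guide 2 and Sik1 guide 2/Sik3 guide 2 were among those lost (exact permutation adjusted p up to 0.0699). Triple bU6-Lkb1 guide 1, triple mU6-Lkb1 guide 1 and triple hU6-Lkb1 guide 2 lost their call without any 1 of the 4 KT mice, the former also without KT_Cas9 replicate 2 or 3 (exact permutation adjusted p up to 0.0959). The count was 9 on the 90th percentile of tumour size, 8 on the arithmetic mean and 0 on the median.

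The single-gene Sik vectors had small differences from KT mice, 0.15 ± 0.06 SE for Sik1 guide 1, 0.23 ± 0.09 SE for Sik1 guide 2, 0.09 ± 0.07 SE for Sik3 guide 1 and 0.09 ± 0.07 SE for Sik3 guide 2. None of the 4 passed by exact permutation (lowest adjusted p = 0.160, 0 at an unadjusted p under 0.05, 0 in edgeR and 0 in limma), and their mean was 0.14 ± 0.06 SE (exact permutation adjusted p = 0.256). Without KT_Cas9 replicate 6, Sik1 guide 1 (0.19, exact permutation adjusted p = 0.0224) and Sik1 guide 2 (0.27, adjusted p = 0.0399) passed, and the mean was 0.18 (exact permutation p = 0.0224). The other AMPK-related kinases, which share with the Siks their activation by Lkb1, lay near 0 against KT mice, with 0.08 ± 0.05 SE for dual Ampk1/Ampk2, 0.00 ± 0.14 SE for triple Ampk1/Ampk2, -0.11 ± 0.08 SE for Nuak1/Nuak2, -0.01 ± 0.05 SE for Mark2/Mark3/Mark4 and 0.04 ± 0.11 SE for Snrk (0 of 5 passed by exact permutation, 0 at an unadjusted p under 0.05, 0 in edgeR and 0 in limma). Against inert tumours of the same KT_Cas9 mice, 18 of the 24 vectors were larger by exact sign-flip permutation. The count was 0 with sizes summarised by the median or with the size floor 10 times higher, which leaves 6 KT_Cas9 mice. The 18 included Sik1 guide 1 (0.20 ± 0.17 SD), Sik1 guide 2 (0.26 ± 0.24 SD), Sik3 guide 1 (0.16 ± 0.21 SD) and triple mU6-Lkb1 guide 2 (0.19 ± 0.16 SD, n = 10). In KT mice no vector passed by exact sign-flip (0 of 24, 0 at an unadjusted p under 0.05), where 4 mice allow no p below 0.125.

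**Figure D2:**
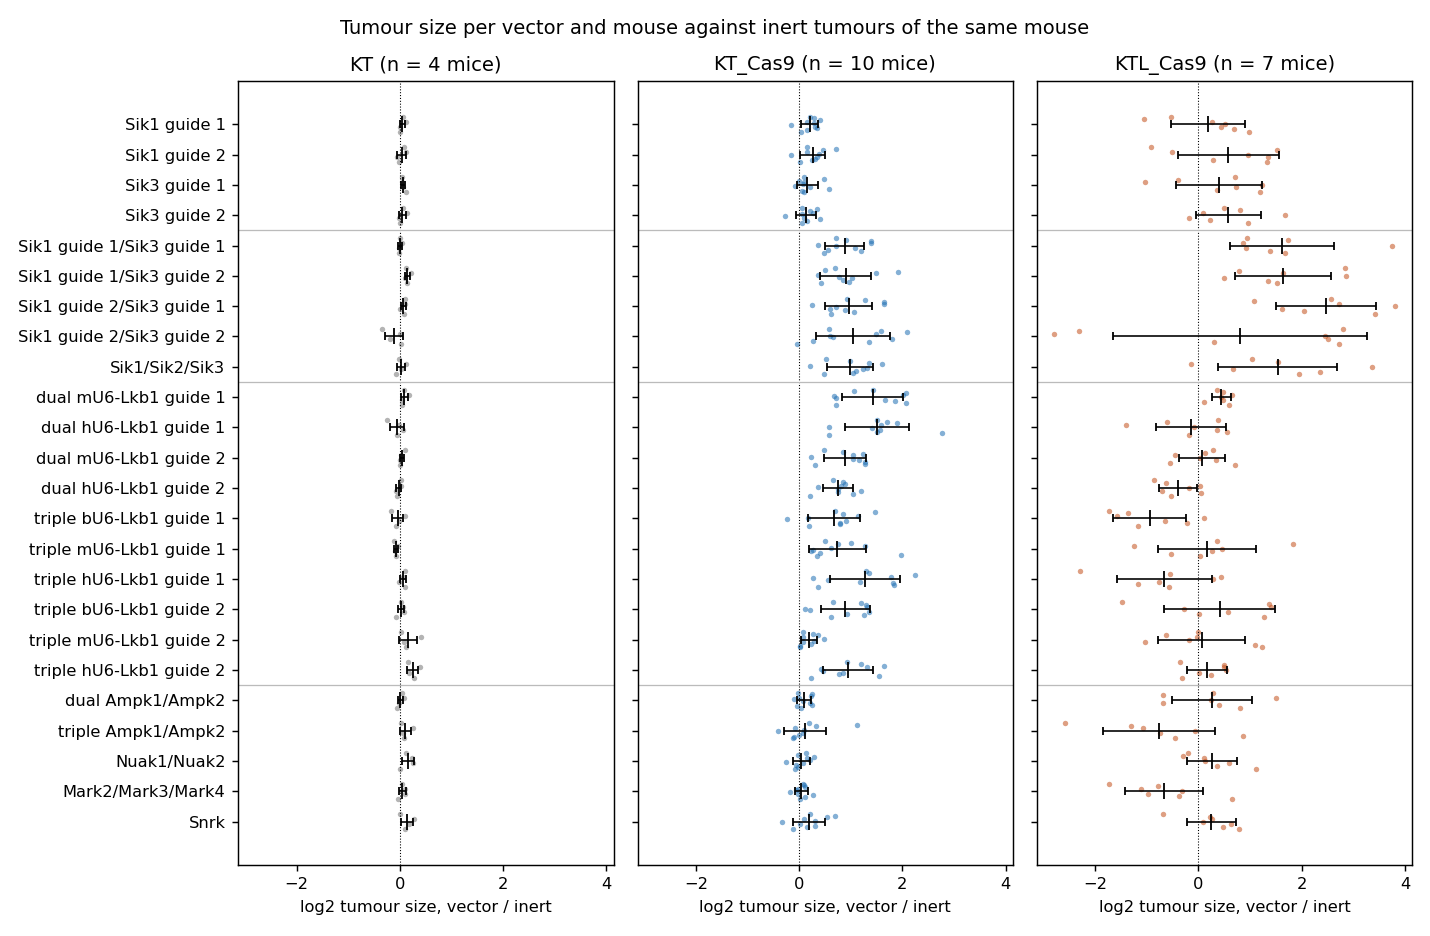
Tumour size per vector as log2 ratio to the inert tumours of the same mouse, for KT, KT_Cas9 and KTL_Cas9 mice, with points for mice and bars for mean ± SD. The dual Sik1/Sik3 and Lkb1 vectors lie above 0 in KT_Cas9 mice (Sik1 guide 1/Sik3 guide 1 at 0.88, dual hU6-Lkb1 guide 1 at 1.51), and in KTL_Cas9 mice Sik1 guide 2/Sik3 guide 1 lies at 2.46 and dual hU6-Lkb1 guide 1 at -0.14.

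Comparisons of vectors within the same mice ask whether Sik1 and Sik3 act together and how far the vector design mattered. In KT_Cas9 mice the dual Sik1/Sik3 vectors exceeded the sum of their single-gene vectors by 0.56 ± 0.50 (SD, n = 10) on the log2 scale, in 8 of 10 mice. Sik1/Sik2/Sik3 lay 0.10 ± 0.28 (SD, n = 10) above Sik1 guide 1/Sik3 guide 1. The former is a triple and the latter a dual vector, so this does not separate the effect of the Sik2 guide. The Lkb1 and Sik multi-gene means differed by -0.03 ± 0.24 (SD, n = 10). As a mean of 5 promoter positions, Lkb1 guide 1 gave larger tumours than guide 2, by 0.39 ± 0.27 (SD) in 9 of 10 mice. At the triple bU6 position alone the order was reversed, with 0.68 for guide 1 and 0.89 for guide 2 against inert. Within the triple vectors the hU6 position exceeded the mU6 position by 0.64 ± 0.46 (SD) in 9 of 10 mice. The mU6 position gave larger tumours in dual than in triple vectors (0.69 ± 0.43 SD, 9 of 10 mice), and the value for hU6 was 0.03 ± 0.33 SD. In the 4 KT mice, without Cas9, the dual-minus-sum contrast was -0.08 and the guide contrast -0.10, each above 0 in 0 of 4 mice. There triple hU6 minus mU6 was 0.11 (above 0 in 4 of 4), dual minus triple was 0.02 for mU6 (3 of 4) and -0.19 for hU6 (0 of 4), and contrasts were not tested between KT_Cas9 and KT mice. By two-sided exact sign-flip permutation, adjusted over 14 contrasts, the dual-minus-sum, guide, hU6-minus-mU6 and dual-minus-triple mU6 contrasts each had adjusted p = 0.0273. The contrast of Sik1/Sik2/Sik3 with its dual vector had exact adjusted p = 0.378 and the Lkb1-minus-Sik contrast 0.805. Each of those 4 contrasts had adjusted p = 0.0547 without KT_Cas9 replicate 1, 3, 4 or 9, and none passed on median sizes (0.04 to 0.10, lowest adjusted p = 0.164). The dual-minus-sum contrast did not pass on the 90th percentile either (0.36, adjusted p = 0.204). In KTL_Cas9 mice the dual vectors exceeded the sum by 0.76 ± 0.87 (SD, n = 7) in 6 of 7 mice and did not pass (exact sign-flip p = 0.0469, adjusted p = 0.164). The sum on the log2 scale is the product of the folds, and cutting efficiency of the guides was not measured.

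The comparison of KTL_Cas9 with KT mice asks which vectors changed tumour size when Lkb1 was already gone. The Sik multi-gene vectors enlarged tumours there too, and the Lkb1 vectors as a class did not pass. As a class the Sik multi-gene vectors averaged a log2 ratio of 1.61 ± 0.99 (SD, n = 7) with 7 of 7 mice above 0, a 3.01-fold difference from KT mice (log2 1.59 ± 0.37 SE, exact permutation p = 0.0121, adjusted p = 0.0364). All 9 Sik vectors together differed by 1.05 ± 0.28 SE (exact permutation p = 0.0152, adjusted p = 0.0379). The Lkb1 vectors, here acting on tumours without Lkb1, averaged -0.09 ± 0.23 (SD, n = 7) with 3 of 7 mice above 0, and differed from KT mice by -0.13 ± 0.09 SE (exact permutation adjusted p = 0.388). As classes the single-gene Sik vectors (0.38 ± 0.21 SE) and other AMPK-related kinases (-0.23 ± 0.20 SE) did not pass. The Sik multi-gene difference was 0.74 (exact permutation p = 0.0606) on median sizes. The all-Sik difference lost its call on the 90th percentile (0.65, exact permutation p = 0.1), on the median (0.41, p = 0.158) and without the inert vector Neo1/NT (1.02, p = 0.0879).

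Vector by vector, 0 of the 24 passed in KTL_Cas9 versus KT by exact permutation after adjustment, while 6 had an unadjusted p under 0.05, and the smallest p that 330 splits allow is 0.00303. The edgeR test on reads called 5 vectors, 4 Sik multi-gene vectors and the single-gene vector Sik3 guide 2 (1.26, adjusted p = 0.0133), and limma on the ratios called 3. Sik1 guide 2/Sik3 guide 1 was 5.25-fold larger (log2 2.39 ± 0.37 SE) and Sik1 guide 1/Sik3 guide 1 was 1.61 ± 0.38 SE higher, each with exact permutation adjusted p = 0.0727. Sik1 guide 1/Sik3 guide 2 was 1.49 ± 0.35 SE higher (exact permutation adjusted p = 0.0909) and Sik1/Sik2/Sik3 1.52 ± 0.44 SE higher (adjusted p = 0.160). The remaining 2 of the 6 were Lkb1 vectors that went opposite ways. Dual mU6-Lkb1 guide 1 was 0.35 ± 0.08 SE higher (exact permutation adjusted p = 0.0909) and triple bU6-Lkb1 guide 1 was lower (-0.91 ± 0.27 SE, adjusted p = 0.170). Adjusted over the list alone, 4 of the 5 Sik multi-gene vectors passed, and 3 of the 9 Sik vectors. The exception was Sik1 guide 2/Sik3 guide 2, at 0.93 ± 0.93 SE, whose ratio was -2.32 in KTL_Cas9 replicate 3 and -2.80 in replicate 4 and from 0.30 to 2.80 in the other mice. Counts of 2 or 3 vectors were called under 6 further settings: 3 on the 95th percentile, without barcodes seen in more than 1 mouse, without the inert vector Neo1/NT/Neo2, and at 10 or more reads, and 2 with the floor 3 or 10 times higher. Against the inert tumours of the same KTL_Cas9 mice, 0 of 24 passed by exact sign-flip (7 at an unadjusted p under 0.05), where the smallest p is 0.0156 and at least 8 vectors would have to reach it.

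The direct test of KTL_Cas9 against KT_Cas9 mice asks whether a vector's effect depends on Lkb1. The Lkb1 vectors had a smaller effect where Lkb1 was already deleted, with the class lower in KTL_Cas9 than in KT_Cas9 mice (log2 difference -1.01 ± 0.15 SE, exact permutation p = 0.000103, adjusted p = 0.00154). Of the 10 Lkb1 vectors, 7 were lower, including triple hU6-Lkb1 guide 1 (-1.94 ± 0.41 SE, exact permutation adjusted p = 0.00185), dual hU6-Lkb1 guide 1 (-1.65 ± 0.32 SE, adjusted p = 0.000617), triple bU6-Lkb1 guide 1 (-1.62 ± 0.31 SE, adjusted p = 0.00123) and dual hU6-Lkb1 guide 2 (-1.16 ± 0.17 SE, adjusted p = 0.000617). Of the Sik vectors only Sik1 guide 2/Sik3 guide 1 passed, with a larger effect in KTL_Cas9 mice (1.504 ± 0.39 SE, exact permutation adjusted p = 0.00296). It was -0.19 on arithmetic means, -0.60 in edgeR on reads and -1.01 with the floor 10 times higher. Sik1 guide 1/Sik3 guide 1 (0.73 ± 0.40 SE, exact permutation adjusted p = 0.0522) passed without KTL_Cas9 replicate 2, 4 or 6 or KT_Cas9 replicate 3 or 4. Sik1 guide 1/Sik3 guide 2 passed without KTL_Cas9 replicate 3 or 6 or KT_Cas9 replicate 3, and Sik3 guide 2 without KTL_Cas9 replicate 4 or 6. Mark2/Mark3/Mark4, microtubule affinity-regulating kinases, was lower (-0.71 ± 0.29 SE, exact permutation adjusted p = 0.0184). It lost its call in 7 of 33 alternatives, being -0.04 in edgeR on reads (adjusted p = 0.927) and -0.0122 with the floor 10 times higher. Triple Ampk1/Ampk2 just failed (-0.88 ± 0.43 SE, exact permutation adjusted p = 0.0522). It passed in limma (adjusted p = 0.0429), without KTL_Cas9 replicate 5 (-0.997) or 7 (-1.15), on the 95th (-0.94) and 90th (-1.15) percentile and with the floor 3 times lower (-1.45). It passed too without barcodes seen in more than 1 mouse (-0.72) or without Neo1/NT (-1.01), and was -0.15 in edgeR on reads (adjusted p = 0.855). In all, 9 of 24 vectors passed, and 14 on the 90th percentile. On median sizes dual mU6-Lkb1 guide 1 was 0.69 (adjusted p = 0.00309) and dual hU6-Lkb1 guide 1 0.23, and the Lkb1 class did not pass, at -0.07.

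As a class the Sik multi-gene vectors did not differ by the test between KTL_Cas9 and KT_Cas9 mice (0.66 ± 0.40 SE, exact permutation p = 0.0771, adjusted p = 0.147). That value had no stable sign across the size floor, being 1.03 (exact permutation p = 0.00273) with the floor 3 times lower, -0.60 (p = 0.191) with it 3 times higher and -1.52 (p = 0.00408) with it 10 times higher. It was -0.39 on the 95th percentile, -0.75 on arithmetic means, 0.61 (exact permutation p = 0.00658) on medians and 0.73 (p = 0.0469) without the inert vector Neo1/NT/Neo2. Without KTL_Cas9 replicate 3 it was 0.83 (exact permutation p = 0.0260), and without replicate 4 it was 0.85 (p = 0.0215).

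The number of tumours per vector, relative to inert tumours, asks whether a vector changed how many cells grew past the floor. No vector changed tumour number by exact permutation in KT_Cas9 versus KT mice (0 of 24, 0 at an unadjusted p under 0.05, 0 by edgeR, lowest adjusted p = 0.474), and 6 did without the 2 KT_Cas9 mice under 500000 reads. Values for the Sik multi-gene and Lkb1 classes were 0.20 ± 0.07 SE and -0.04 ± 0.10 SE. In KTL_Cas9 versus KT mice 0 of 24 passed by exact permutation (5 at an unadjusted p under 0.05, lowest adjusted p = 0.0970). By number 6 passed in edgeR, 6 with the floor 3 times lower and 2 without barcodes seen in more than 1 mouse. Nuak1/Nuak2 had 1.53-fold (log2 0.61 ± 0.14 SE), triple hU6-Lkb1 guide 2 1.28-fold (0.36 ± 0.08 SE) and triple mU6-Lkb1 guide 2 1.27-fold (0.35 ± 0.09 SE) as many tumours relative to inert, each with exact permutation adjusted p = 0.0970. In edgeR the first of these (0.59) and triple hU6-Lkb1 guide 2 (0.39, adjusted p = 0.0286) passed, and triple mU6-Lkb1 guide 2 did not (0.31, adjusted p = 0.0681). The other edgeR calls were triple Ampk1/Ampk2, Snrk, Mark2/Mark3/Mark4 and dual hU6-Lkb1 guide 1. Of the 24 vectors 22 lay above 0 in this comparison, with a median of 0.19, and all share the inert tumours as denominator.

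The size distributions show where the enlargement lay. In KT_Cas9 mice the Sik multi-gene vectors exceeded inert tumours 1.08-fold at the median, 1.28-fold at the 80th, 3.47-fold at the 95th and 8.04-fold at the 99th percentile (log2 3.01 ± 1.45 SD, n = 10). The Lkb1 vectors had a similar profile, with 1.10-fold, 1.38-fold, 3.57-fold and 5.79-fold. In KTL_Cas9 mice the Sik multi-gene vectors exceeded inert tumours 1.65-fold at the median, 2.14-fold at the 80th, 2.65-fold at the 95th and 2.29-fold at the 99th percentile (log2 1.19 ± 1.005 SD, n = 7). The Lkb1 vectors stood there at 1.04-fold, 1.06-fold, 0.936-fold and 0.731-fold. In KTL_Cas9 mice the Sik multi-gene vectors had medians of 26 to 98 tumours per mouse, and inert tumours numbered 61 to 321. The 99th percentile there rests on very few tumours. The Sik multi-gene profiles of the 2 genotypes were not tested against each other beyond the class tests. Of all estimated tumour cells, Sik multi-gene vectors held 18.8 ± 0.537% in KT (SD, n = 4), 33.1 ± 6.77% in KT_Cas9 (SD, n = 10) and 36.5 ± 9.08% in KTL_Cas9 mice (SD, n = 7). Lkb1 vectors held 40.9 ± 0.734%, 50.2 ± 8.18% and 28.4 ± 4.63%, and inert vectors 7.16 ± 0.253%, 2.81 ± 1.79% and 4.82 ± 1.46%. All classes share the same total, so a lower share of a class need not mean smaller tumours.

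**Figure D3:**
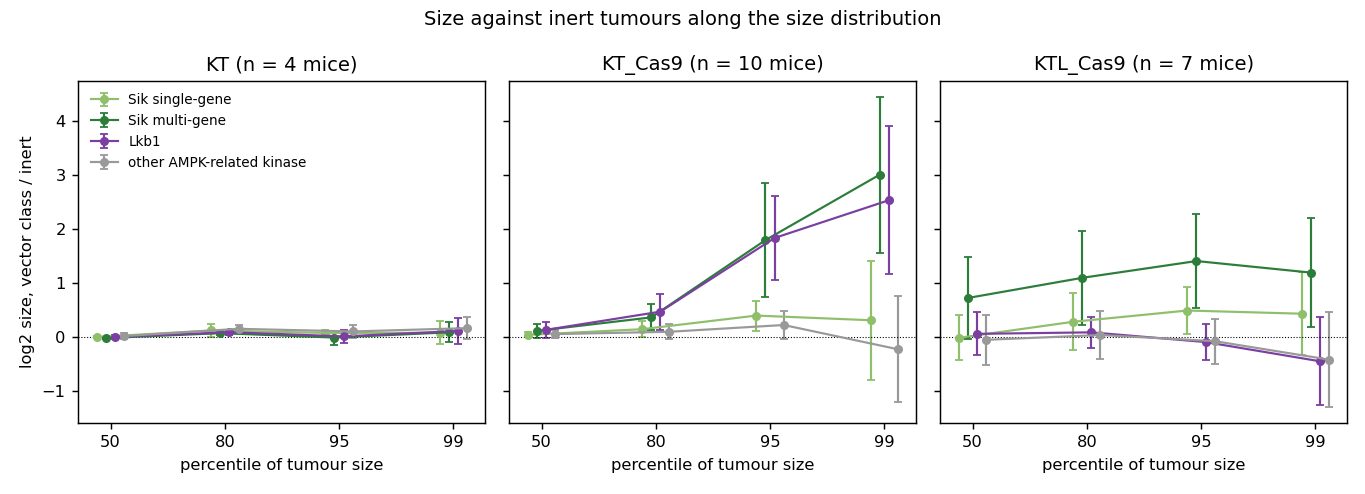
Tumour size at the 50th, 80th, 95th and 99th percentile as log2 ratio to inert tumours of the same mouse, by vector class and mouse group, as mean ± SD over 4 KT, 10 KT_Cas9 and 7 KTL_Cas9 mice. The Sik multi-gene class reaches 3.01 at the 99th percentile in KT_Cas9 mice and lies between 0.72 and 1.41 in KTL_Cas9 mice.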

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

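Tests chosen after the result was seen were those of tumours that kept Lkb1, of a few very large tumours and of carried-over barcodes for the Sik multi-gene vectors in KTL_Cas9 mice, that of shallow libraries, and the values with the floor 10 times higher.

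The effect of Lkb1 vectors differed between genotypes, with the class lower in KTL_Cas9 than in KT_Cas9 mice (log2 difference -1.01, exact permutation adjusted p = 0.00154). By vector the differences were -1.94 for triple hU6-Lkb1 guide 1, -1.65 for dual hU6-Lkb1 guide 1, -1.62 for triple bU6-Lkb1 guide 1, -1.16 for dual hU6-Lkb1 guide 2, -0.98 for dual mU6-Lkb1 guide 1, -0.82 for dual mU6-Lkb1 guide 2 and -0.78 for triple hU6-Lkb1 guide 2. Mark2/Mark3/Mark4 differed by -0.71 and Sik1 guide 2/Sik3 guide 1 by 1.504. For the count of 9, only the real split (1 of 100 splits of the mice) gave as many, and the highest other split gave 2. This argues against chance, but 100 splits cannot exclude it. Single vectors depended on the processing. Mark2/Mark3/Mark4 lost its call in 7 of 33 alternatives (-0.04 in edgeR on reads), and Sik1 guide 2/Sik3 guide 1 lost it in 2 and reversed in 3. Each of the 7 Lkb1 vectors kept direction and call in at least 30 of the 33. For the 14 vectors of KT_Cas9 versus KT chance is likewise argued against but not excluded (1 of 100 splits, highest other 6). The counts of 0 excluded nothing, as 100 of 100 splits gave at least as many: the highest other split gave 3 for size in KTL_Cas9 versus KT, 7 for number in KT_Cas9 versus KT and 0 for number in KTL_Cas9 versus KT. Only 4 of the 100 splits called any vector by number in KT_Cas9 versus KT. A split calling 7 may reflect a structure among those mice other than Cas9, or chance in the inert tumours that all vectors share as denominator, and neither was tested.

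Sik multi-gene vectors gave larger tumours in KTL_Cas9 than in KT mice (1.59 ± 0.37 SE). Tumours that kept Lkb1 would have grown with Lkb1 vectors as with Sik vectors, but within KTL_Cas9 mice the Lkb1 mean lay below the Sik multi-gene mean by -1.70 ± 0.37 SE, in 7 of 7 mice, which argues against them as the whole cause. The exact sign-flip p of 0.0156 was the smallest that 7 mice allow, and it did not pass after adjustment over the 14 contrasts (adjusted p = 0.164). A few very large tumours would leave the median alone, and the median difference was 0.74 ± 0.29 SE, above 0 by over 2 SE. Its exact permutation p of 0.0606 did not pass, and the reason was not tested. Barcodes carried over between libraries are argued against by 1.15 ± 0.27 SE without barcodes seen in more than 1 mouse (exact permutation p = 0.00606). KTL_Cas9 and KT mice also differ in Lkb1 and in Cas9 itself. Sizes are ratios to inert tumours of the same mouse, so an effect of either on all its tumours alike cancels. Within KTL_Cas9 mice the class lay 1.61 above inert in 7 of 7 mice (exact sign-flip p = 0.0156, adjusted p = 0.0391 over the classes), and in KT mice at 0.02. These values argue against such a shared effect for this class. Loss of the Sik genes themselves was not measured and stays open.

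Triple mU6-Lkb1 guide 2 was the only Lkb1 vector that did not pass in KT_Cas9 versus KT (0.03 ± 0.10 SE). A weaker guide and a weaker position acting additively predict 0.39 against inert, and the observed value lay -0.20 ± 0.16 SE from that (exact sign-flip p = 0.281, below in 4 of 10 mice), so this explanation stays open. A vector without a working Lkb1 guide predicts no change in the upper tail either, and the 99th percentile differed from KT by 0.0313 ± 0.46 SE (exact permutation p = 0.960), against 2.42 for the Lkb1 class, so it stays open too. Either may account for the vector, and no biological explanation was tested.

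The Sik multi-gene difference between KTL_Cas9 and KT_Cas9 mice turned its sign with the size floor, from 0.66 to -1.52 with the floor 10 times higher. Different mice being left at the higher floor is argued against, since the mice left there gave 0.52 ± 0.42 SE at the original floor. These 13 mice all had at least 500000 reads, and in them the difference changed by -2.04 ± 0.24 SE from the original floor to the higher one. Libraries under 500000 reads are therefore argued against by the same comparison, not by a separate one. Depth among the 13 mice was not tested. A floor at another relative size in larger tumours cannot be told apart from a real difference, because with floors in proportion to inert size (500 to 55758 cells) the value was -0.20 ± 0.39 SE (exact permutation p = 0.605), between both. Whether Lkb1 loss changes the effect of Sik loss also stays open as the genotypes' own difference.

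Single mice far from the others of their group appeared in 5 of 75 groups tested, against 3.75 by chance (about 1 in 20). They were KT replicate 3 for Sik1 guide 2/Sik3 guide 1 (log2 ratio 0.0139, all others 0.09), KT replicate 1 for dual mU6-Lkb1 guide 2 (0.11, others 0.01 to 0.03), KT_Cas9 replicate 6 for Sik3 guide 2 (-0.28, others 0.05 to 0.40), KT_Cas9 replicate 2 for triple Ampk1/Ampk2 (1.13, others -0.41 to 0.32) and KTL_Cas9 replicate 5 for Sik1 guide 1/Sik3 guide 1 (3.76, others 0.87 to 1.74).

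Reads without a vector name, which no comparison uses, exceeded the highest share in KT mice (1.27%) in 9 mice. The shares were 26.8% in KTL_Cas9 replicate 1, which was left out, 10.4% in KT_Cas9 replicate 2, 9.63% in replicate 4, 2.58% in replicate 6, 2.15% in replicate 8, 1.46% in replicate 1, 1.43% in replicate 3, and 1.33% and 1.31% in KTL_Cas9 replicates 5 and 3. In KT_Cas9 replicate 4 a single unnamed barcode held 276209 reads, 8.32% of that mouse's reads.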

How the results depend on the processing

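Added after seeing the data were the floor 10 times higher, at least 10 reads per tumour, mice under 500000 reads left out and minor copies left out. Over 40 settings and 173 results, 4599 alternative values were computed, not counting mice outside a comparison or the merge that merged nothing. The larger inert tumours of KTL_Cas9 than KT_Cas9 mice kept their direction and call in all settings run for them (4.65 to 5.05 on leaving out each mouse). The Sik multi-gene difference between KT_Cas9 and KT kept both too, at 0.85 to 0.997 on leaving out each mouse. On medians that class stood at only 0.11 in KT_Cas9 and -0.02 in KT mice, where median inert sizes lay close to the floor. For class differences and inert size, a call in these settings was an exact permutation p under 0.05 without adjustment. Of the single-vector size results, 1887 alternatives kept direction and call, 67 gained a call, 65 lost it, 12 reversed and 129 changed sign without a call on either side. Of those on number 1019 kept both, 20 gained a call and 89 changed sign without a call. Of the contrasts 508 kept both, 6 gained a call, 71 lost it and 45 changed sign without a call. Of the other class differences the numbers were 225, 8, 2 and 17. Merging at 1 mismatch merged 0 barcodes, so it tests nothing. Leaving out each spike-in was not run, since the table gives 1 mean per mouse. Depth limits small tumours: the floor lies at 3.13 reads in the KT mouse with fewest, and KTL_Cas9 mice hold 61 to 321 inert tumours. The cause was not tested for the values below, except that a floor 10 times higher leaves 6 and one 3 times higher 8 KT_Cas9 mice.

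The 14 vectors with changed size in KT_Cas9 versus KT became 9 on the 90th percentile, 0 on the median and 8 on the arithmetic mean, and 9 to 16 on leaving out each mouse. The 18 off inert in KT_Cas9 became 0 on the median and 0 with the floor 10 times higher. The 0 by size in KTL_Cas9 versus KT became 3 on the 95th percentile, 2 with the floor 3 times higher, 3 without barcodes seen in more than 1 mouse, 3 without Neo1/NT/Neo2, 5 in edgeR, 3 in limma, 3 at 10 or more reads and 2 with the floor 10 times higher. The 9 differing between KTL_Cas9 and KT_Cas9 became 14 on the 90th percentile. By number, the 0 in KT_Cas9 versus KT became 6 without mice under 500000 reads, and the 0 in KTL_Cas9 versus KT became 6 with the floor 3 times lower, 2 without barcodes seen in more than 1 mouse and 6 in edgeR.

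Inert size in KT_Cas9 versus KT (-0.70) was -0.38 on the arithmetic mean, -0.68 with the floor 3 times lower, -0.21 with it 3 times higher, -0.77 at 10 or more reads, 0.0344 on shares of reads and 0.23 with the floor 10 times higher. On medians the all-Sik difference in KT_Cas9 versus KT was 0.0922, and in KTL_Cas9 versus KT the Sik multi-gene difference was 0.74 and the all-Sik difference 0.41, the latter being 0.65 on the 90th percentile and 1.02 without Neo1/NT. Between KTL_Cas9 and KT_Cas9, Sik multi-gene (0.66) and all Sik (0.47) were -0.39 and -0.17 on the 95th percentile, -0.75 and -0.31 on the arithmetic mean, 1.03 and 0.69 with the floor 3 times lower, -0.60 and -0.18 with it 3 times higher, 0.73 and 0.54 without Neo1/NT/Neo2, and -1.52 and -0.83 with the floor 10 times higher. Sik multi-gene was 0.61 on medians, and leaving out each mouse gave 0.39 to 0.85 and 0.27 to 0.63.

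Reversed vectors in KTL_Cas9 versus KT_Cas9 with the floor 10 times higher were Sik1 guide 1/Sik3 guide 1 (-1.41), Sik1 guide 1/Sik3 guide 2 (-1.32), Sik1 guide 2/Sik3 guide 1 (-1.01) and Sik1/Sik2/Sik3 (-2.002). Sik1 guide 2/Sik3 guide 1 was also -0.19 on the arithmetic mean and -0.60 in edgeR. On medians dual mU6-Lkb1 guide 1 was 0.69, dual hU6-Lkb1 guide 1 0.23 and dual mU6-Lkb1 guide 2 0.19; dual mU6-Lkb1 guide 1 was 0.41 with the floor 3 times lower, and Snrk -0.47 on the 90th percentile. In KT_Cas9 versus KT, triple mU6-Lkb1 guide 2 was -0.11 with the floor 3 times lower.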

Other observations

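The comparison of tumour number between KTL_Cas9 and KT_Cas9 mice and the counts of largest tumours were chosen after the data were seen. Among the 20 largest tumours of each mouse, Sik multi-gene vectors made up 16 of 80 in KT mice, 82 of 200 (41%) in KT_Cas9 and 83 of 140 (59.3%) in KTL_Cas9 mice. Lkb1 vectors made up 31 of 80, 101 of 200 (50.5%) and 18 of 140 (12.9%), and inert vectors 8, 2 and 7. Sik multi-gene vectors held 18.6%, 20.9% and 17.1% of all tumours in the same groups, and Lkb1 vectors 41.0%, 37.9% and 40.5%. The median number of tumours per mouse was 41380, 8226 and 1685. The 20 largest are thus a smaller part of all tumours in KT than in KTL_Cas9 mice, and the groups are not compared at the same percentile.

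Relative to inert tumours, Nuak1/Nuak2 vectors had 1.39-fold and triple mU6-Lkb1 guide 2 had 1.24-fold as many tumours in KTL_Cas9 as in KT_Cas9 mice (exact permutation adjusted p = 0.0469 each), the 2 of 24 vectors that passed. In edgeR on tumour numbers Nuak1/Nuak2 (0.49), triple Ampk1/Ampk2 (0.55) and dual hU6-Lkb1 guide 1 (0.48) passed, and triple mU6-Lkb1 guide 2 did not (0.30, adjusted p = 0.0986). On the log2 scale the exact test's 2 vectors were at 0.47 and 0.31, while the median of the 24 vectors was 0.18 and 18 lay above 0. All vectors share the inert tumours as denominator, and a shift in these was not separated from a common change of the targeting vectors. In KTL_Cas9 versus KT the other AMPK-related kinases as a class had 0.40 ± 0.11 SE more on the log2 scale (exact permutation p = 0.0242, adjusted p = 0.182).

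In KTL_Cas9 mice Sik1 guide 2/Sik3 guide 2 had 9 to 90 tumours per mouse, with a median of 26, and the widest spread of the multi-gene Sik vectors (SD 2.46, against 0.97 for Sik1 guide 2/Sik3 guide 1).

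Pairs of mice shared a median of 55 barcodes of the same vector over 231 pairs. The highest number was 1513, between KT replicate 1 and KT_Cas9 replicate 5, then 630 between KT_Cas9 replicates 3 and 4. Barcodes seen in more than 1 mouse held a median of 4.99% of the reads in KT, 36.6% in KT_Cas9 and 15.5% in KTL_Cas9 mice. Their minor copies held at most 0.0758%, 3.67% and 0.00297%. These shares cover the 21 mice of the comparisons. KTL_Cas9 replicate 1, which is in the 231 pairs but not in these shares, had 34.6% and 0.0734%.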
